A study of Homo sapiens with 8 samples.

How the data were processed

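RNA of the breast cancer line HCC1937 and of HCC1937 with exogenous wild-type BRCA1, with or without 10 µM COH29 for 24 h, was hybridised to 8 Affymetrix arrays, 2 per group. Per the labels' protocols, cells grew in RPMI medium with 10% fetal bovine serum, total RNA was isolated with TRIzol and biotin-labelled by a one-cycle protocol. The deposited values are log2 intensities of 33297 probe sets on each array. RMA and Partek are named in the submitters' processing notes, with no version. RMA corrects the background, makes the arrays' distributions equal and summarises the probes of a probe set on the log2 scale. The sorted values of the 8 arrays differed by at most 0.297, as after such a step. The deposited table was used as it stands. No genome build was named in the sources used here, so no coordinates are given. No detection p was used, and the number of arrays limits the precision. Scan dates, batches and the scanner files were not used here.

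Probe sets were named from the platform annotation, in which 19460 had 1 gene, 1754 had several and 12083 had none. Probe sets with several genes or none stayed out of the tests. Of the named probe sets, 19429 matched a current symbol in RefSeq's human gene table (assembly GRCh38.p14), which was also used to find neighbouring genes, and 0 symbols changed. For each gene the probe set with the highest mean over the 8 arrays was kept, which left 18417 genes, 769 of them chosen among several probe sets.

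A group-means model was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), since 2 arrays per group alone leave few residual degrees of freedom. It had 4 residual degrees of freedom. Contrasts were COH29 minus control in each line, the difference of these effects (HCC1937 minus HCC1937+BRCA1), HCC1937+BRCA1 minus HCC1937 without drug, and the mean drug effect of both lines. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those of the moderated fit. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

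Before the data were examined, 30 gene lists were fixed, covering deoxynucleotide supply, DNA repair, replication, the cell cycle, stress responses, signalling, metabolism and cell type markers. Some lists share members, such as SLC7A11 (integrated stress response and NRF2) and RRM2B (deoxynucleotide supply and p53 targets). Such lists are not separate measurements. Each was tested with camera at an inter-gene correlation of 0.01, with adjustment over 150 tests, and members past the threshold were counted over all genes and adjusted over the list alone. With the correlation estimated from the residuals, camera called 0 lists in any comparison, with the smallest adjusted p at 0.119. That setting also tests on the 4 residual degrees of freedom. Metallothionein and zinc genes had an estimated correlation of 0.000567, under the preset 0.01. Their camera adjusted p for the difference of effects still went from 1.56e-08 to 0.119. The lost calls thus do not come from gene correlation alone, and 0 calls do not by themselves show unmoved lists. The test fry calls a list whose genes move, on balance, one way, without comparing it with other genes.

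The rule for named genes was also fixed beforehand. It names BRCA1, RRM1, RRM2, RRM2B, CDKN1A and 1 further gene that is not reported here, the 10 largest rises and falls per comparison among called genes whose arrays did not overlap (5 and 5 for the difference of effects), and the 4 members with the smallest p of each list with a camera call or at least 3 called members. Names were left out for length.

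The fit was tested on simulated data for COH29 in HCC1937 with 18417 genes, 200 of them changed. All genes changed by 1 or 2 on the log2 scale were recovered (100% of 67 and 66), as were 56.7% of the 67 changed by 0.5. In this single draw 18 unchanged genes were called, a share of the calls above the nominal 0.05. Noise was drawn independently for each gene from the moderated spread, and the real comparison called 4179 genes. Recovery and error may thus differ in the real data.

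Alternatives fixed beforehand were leaving out genes below the 30th percentile of mean level, shifting each array to one median, cyclic loess, eBayes with trend and robust, no moderation, the replicate number as a replicate block, the mean of a gene's probe sets, a minimum log2 change of 1, only the 4 arrays compared, and leaving out each array. For lists they were an estimated correlation, the replicate block and fry. Cyclic loess for lists and a block with numbers crossed between the lines were added after seeing the data.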

Results

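Gene expression was measured on 8 Affymetrix arrays in a breast cancer cell line, HCC1937, which carries a truncated BRCA1, and in the same line given exogenous wild-type BRCA1, called HCC1937+BRCA1 in the series design and HCC1937BRCA1 in the sample titles. Each line was left without COH29 or exposed to it for 24 h at 10 µM. COH29 is an inhibitor of ribonucleotide reductase, the enzyme that makes deoxynucleotides for DNA synthesis. No hours are recorded here for the control arrays and no vehicle is named, so untreated means without COH29. Effects of a vehicle or of culture time cannot be told apart from those of the drug. The 4 resulting groups held 2 arrays each. Values were log2 intensities, and 18417 genes were tested. The arrays of a group correlated across genes with r between 0.996 and 0.997, and each array was most similar to the other array of its own group. The first principal component held 57.2% of the variance and separated the lines, and the second held 32.3% and separated treated from untreated arrays. With 2 arrays per group, the number of arrays limits the precision. The median standard error of a log2 change between groups was 0.103. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

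BRCA1, the gene that defines the lines, was measured at 10.55 ± 0.13 (mean log2 intensity ± SD, n = 2) in HCC1937 control and at 10.46 ± 0.05 in HCC1937+BRCA1 control. The difference of -0.08 ± 0.10 (SE) was smaller than its error (limma adjusted p = 0.62). With COH29 the levels were 10.43 ± 0.04 and 10.16 ± 0.12. On the arrays of both labels BRCA1 lay at percentile 82.7 to 88.6 of the genes, so its signal was high also without the exogenous gene. That argues that the probe set reads transcript of the truncated gene, although signal from other sequences was not tested. How well it reads the exogenous transcript is not given in the sources used here, so the level does not check the line labels. The names HCC1937 and HCC1937+BRCA1 below stand for the arrays labelled HCC1937 and HCC1937BRCA1.

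COH29 in HCC1937 raised SERPINI1, which encodes the protease inhibitor neuroserpin, by 3.48 ± 0.12 on the log2 scale (SE, n = 2 arrays per group). NDRG1, a gene induced by hypoxia and stress, rose by 2.80 ± 0.09. The stress transcription factor gene DDIT3 (CHOP), the stress cytokine gene GDF15 and the glutathione-degrading enzyme gene CHAC1 rose by 2.47, 2.43 and 2.37. The largest falls were in METTL4 (-2.28 ± 0.09), a methyltransferase gene, in RBBP6 (-2.26 ± 0.08), which encodes a ubiquitin ligase that binds RB1, in the histone gene H2BC3 (-2.09 ± 0.17) and in PCF11 (-2.07 ± 0.15), a transcription termination factor gene. ULBP1, which encodes a ligand of the natural killer cell receptor NKG2D, rose by 2.29, and CYP1B1, a cytochrome P450 gene, fell by 1.99 on the log2 scale. In all, 1872 genes were higher and 2307 lower with COH29 in HCC1937, and 172 and 179 of them changed at least 2-fold. With each array shifted to the same median, 52.1% of the calls were higher in place of 44.8%, so the more frequent direction turned. Without HCC1937 COH29 replicate 1 the 4179 calls became 2642, 1333 higher and 1309 lower. Without HCC1937 control replicate 1 or control replicate 2 they became 2392 or 2336.

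In HCC1937+BRCA1, COH29 raised CHAC1 by 4.47 ± 0.08 (SE, n = 2 arrays per group), ULBP1 by 3.98 ± 0.20, STC2, a secreted glycoprotein gene of the stress response, by 3.50 ± 0.08, and DDIT3 by 3.40 ± 0.11. ASNS (asparagine synthetase) rose by 3.38, SERPINI1 by 3.27 and the lipase inhibitor gene ANGPTL4 by 3.02. YAE1 fell by 2.72 on the log2 scale. The chemokine gene CXCL1 fell by 2.68, H2BC3 by 2.59, METTL4 by 2.58 and the hyaluronan synthase gene HAS2 by 2.47. In this line 2498 genes were higher and 3697 lower, with 285 and 390 of them changed at least 2-fold. With each array shifted to the same median, the median change of all genes was 0.11 in place of 0.04, and 54.4% of the calls were higher in place of 40.3%.

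The ribonucleotide reductase genes had smaller changes. RRM2B, the stress-inducible small subunit, rose by 0.82 ± 0.08 in HCC1937 (adjusted p = 0.00021) and by 0.75 ± 0.08 in HCC1937+BRCA1 (adjusted p = 0.000164). RRM2, the S-phase small subunit, rose by 0.31 ± 0.09 in HCC1937 (adjusted p = 0.0417), while its change in HCC1937+BRCA1 was -0.04 ± 0.09 (adjusted p = 0.77). The difference between these effects did not pass the interaction test (adjusted p = 0.305). RRM1, the large subunit, was at -0.16 ± 0.09 in HCC1937 (adjusted p = 0.252) and fell by 0.30 on the log2 scale in HCC1937+BRCA1 (adjusted p = 0.0336). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.41 ± 0.13 and 1.62 ± 0.13. BRCA1 was at -0.12 ± 0.10 in HCC1937 (adjusted p = 0.444) and fell by 0.30 on the log2 scale in HCC1937+BRCA1 (adjusted p = 0.0441). The RRM2 call ended without HCC1937 control replicate 1 (adjusted p = 0.192) or 2 (0.113), HCC1937 COH29 replicate 1 (0.0966) or 2 (0.127), or either HCC1937+BRCA1 control array (0.0538). Without HCC1937+BRCA1 COH29 replicate 2, control replicate 1 or control replicate 2, the adjusted p was 0.19, 0.166 and 0.0626 for RRM1 and 0.226, 0.189 and 0.08 for BRCA1. It was 0.0541 for RRM1 without either HCC1937 control array, and 0.0527 for BRCA1 without either HCC1937 COH29 array. After cyclic loess the changes of RRM1 and BRCA1 were -0.20 and -0.19 (adjusted p = 0.103 and 0.177), and with arrays shifted to one median -0.23 and -0.24 (adjusted p = 0.0833 and 0.103). Of the 16 measured genes of deoxynucleotide supply, 3 rose and 3 fell in HCC1937, and 1 rose and 5 fell in HCC1937+BRCA1 (3, 3, 1 and 7 adjusted over the list alone), with camera adjusted p = 0.75 and 0.174. Over the alternatives 1 to 3 rose and 1 to 3 fell in HCC1937, and 3 to 8 fell in HCC1937+BRCA1. In HCC1937, 1 rose without COH29 replicate 2 or either control array of that line, and 1 fell without control replicate 1. In HCC1937+BRCA1, 3 fell without COH29 replicate 2 of that line or any 1 of the 4 control arrays.

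**Figure D1:**
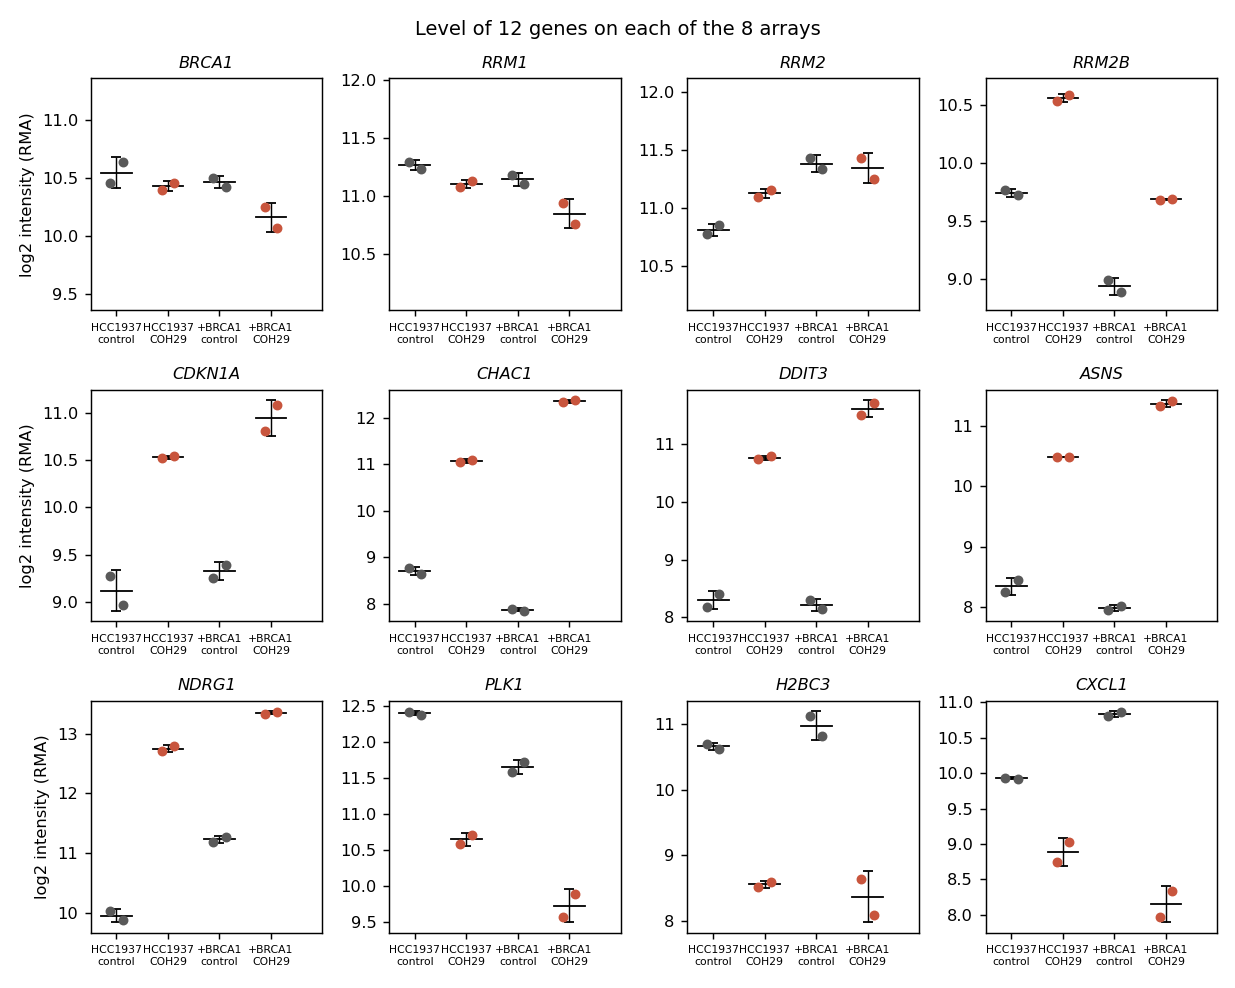
Log2 intensity (RMA) of 12 genes on the 8 arrays, with control arrays in grey and COH29 arrays in red; the horizontal line is the group mean and the bar the SD of 2 arrays. BRCA1 means lie between 10.16 and 10.55, whereas CHAC1 rose by 2.37 in HCC1937 and 4.47 in HCC1937+BRCA1; the axes do not start at 0 and differ between genes.

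The integrated stress response list, genes driven by the transcription factors ATF4 and CHOP, rose in both lines. In HCC1937, 23 of its 27 measured members rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 1.02. In HCC1937+BRCA1, 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 1.57. STC2 and ASNS rose by 2.25 and 2.13 in HCC1937, beside DDIT3 and CHAC1. Camera placed the list above other genes in both lines (adjusted p = 6.62e-20 and 2.81e-21), and with an estimated correlation the adjusted p was 0.119 in each. The unfolded protein response of the endoplasmic reticulum had 12 of 21 members higher in HCC1937 and 13 in HCC1937+BRCA1 (15 and 15 adjusted over the list alone). The co-chaperone gene DNAJB9 rose by 1.74 and 2.61, HERPUD1 by 1.60 and 2.36, and the chaperone gene HSPA5 (BiP) by 0.78 and 1.06. Camera gave adjusted p = 1.21e-06 and 4.89e-06, and adjusted p = 0.245 with an estimated correlation in both lines.

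Hypoxia-inducible genes rose as a group. In HCC1937, 24 of 30 rose and 1 fell (26 and 1 adjusted over the list alone). In HCC1937+BRCA1, 25 rose and 0 fell (25 and 0 adjusted over the list alone). NDRG1 rose by 2.80 and 2.12, the histone demethylase gene KDM3A by 2.02 and 2.01, the mitophagy receptor gene BNIP3 by 2.21 and 1.74, and ANGPTL4 by 1.83 and 3.02. In camera, the adjusted p was 4.16e-15 and 1.58e-16, and the adjusted p was 0.245 with an estimated correlation in both lines. Immediate early and AP-1 genes also rose, 14 of 27 in HCC1937 with 0 lower, and 21 in HCC1937+BRCA1 with 1 lower (14, 0, 21 and 1 adjusted over the list alone). Without HCC1937 control replicate 2 the 14 became 9. JUN rose by 1.06 and 2.02, and the growth factor gene HBEGF by 1.80 and 2.81. Camera gave adjusted p = 9.25e-06 and 3.2e-09, and adjusted p = 0.486 and 0.391 with an estimated correlation. Cholesterol synthesis genes followed, 11 of 20 higher and 1 lower in HCC1937, and 10 higher and 0 lower in HCC1937+BRCA1 (11, 1, 11 and 2 adjusted over the list alone). LPIN1, a list member that does not encode an enzyme of cholesterol synthesis, rose by 1.34 and 1.02, and TM7SF2 by 1.24 in both lines. For the list, the camera adjusted p was 4.95e-05 and 0.00239, and the adjusted p was 0.455 and 0.518 with an estimated correlation. Of 13 metallothionein and zinc transport genes, 5 rose and 1 fell in HCC1937, and 10 rose and 1 fell in HCC1937+BRCA1 (6, 1, 10 and 1 adjusted over the list alone). The list's camera adjusted p was 0.0826 in HCC1937 and 4.95e-05 in HCC1937+BRCA1, the second with an adjusted p = 0.241 under an estimated correlation. MT1X rose by 0.78 and 1.83. Over the alternatives 2 to 6 of these genes rose in HCC1937, with 2 without either COH29 array or control replicate 2 of that line and 3 without control replicate 1. Metallothionein genes are close paralogs whose probe sets may share signal, so the members counted may not be separate measurements.

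Genes of G2/M and mitosis fell. In HCC1937, 34 of 38 measured members fell and 0 rose, with a median of -0.84. In HCC1937+BRCA1, 37 fell and 0 rose, with a median of -0.94 (38 fell in each line adjusted over the list alone). The mitotic kinase gene PLK1 fell by 1.75 and 1.93 on the log2 scale, AURKA by 1.71 and 1.66, the cyclin gene CCNB1 by 1.35 and 1.52, and the spindle checkpoint gene BUB1B by 1.31 and 1.69. Camera gave adjusted p = 3.57e-26 and 5.33e-21, and adjusted p = 0.245 and 0.255 with an estimated correlation. Of 50 replication-dependent histone genes, 26 fell and 9 rose in HCC1937, and 32 fell and 9 rose in HCC1937+BRCA1 (29, 10, 33 and 10 adjusted over the list alone). Without HCC1937 control replicate 1 the 26 became 16, and without moderation of the variances the 9 in HCC1937 became 5. Many histone genes are close paralogs whose probe sets may share signal, so the members counted may not be separate measurements. H2BC3 and the linker histone gene H1-3 (-1.47 and -2.04) fell, while H2BC21 rose by 1.91 and 1.84 and H4C8 by 1.32 and 1.27. By camera the adjusted p was 3.3e-05 and 6.54e-07, and the adjusted p was 0.363 and 0.308 with an estimated correlation. Of 23 G1/S and E2F genes, 4 rose and 5 fell in HCC1937, and 4 rose and 9 fell in HCC1937+BRCA1 (4, 5, 4 and 9 adjusted over the list alone), with camera adjusted p = 0.533 and 0.181. Over the alternatives 2 to 5 rose and 2 to 8 fell in HCC1937. The 4 became 2 without control replicate 2 of that line, and the 5 became 3 without COH29 replicate 1 and 2 without control replicate 1. CDKN2B, the p15 inhibitor gene, rose by 1.32 in both lines, and RB1 fell by 0.68 and 0.66 on the log2 scale.

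DNA repair genes are named in the purpose of the series, and their changes were smaller. Of 39 genes of homologous recombination and the Fanconi anemia pathway, 11 fell and 2 rose in HCC1937, and 21 fell and 0 rose in HCC1937+BRCA1 (12, 2, 21 and 0 adjusted over the list alone). Over the alternatives the counts in HCC1937 ran from 4 to 12 lower and from 0 to 5 higher. Without COH29 replicate 1 or control replicate 2 of that line 4 fell, and without control replicate 1 6 fell. Without COH29 replicate 2 or control replicate 1 0 rose, and without control replicate 2 1 rose. The list medians were -0.14 and -0.30. GEN1, a Holliday junction resolvase gene, fell by 1.39 and 1.03 on the log2 scale, FANCB by 0.83 and 1.19, and RAD50 by 0.63 and 0.73. Camera gave adjusted p = 0.0101 and 2.13e-05, and adjusted p = 0.564 and 0.455 with an estimated correlation. After cyclic loess, an alternative for lists chosen after seeing the data, the camera adjusted p in HCC1937 was 0.0981. In base excision and single-strand break repair, 3 of 22 rose and 4 fell in HCC1937, and 3 rose and 6 fell in HCC1937+BRCA1 (3, 4, 3 and 6 adjusted over the list alone), with camera adjusted p = 0.248 and 0.113. Without HCC1937 control replicate 1 or 2 the 4 became 2, and the 3 higher there became 0 or 1, and 1 without COH29 replicate 2. The glycosylase gene NEIL3 fell by 0.94 and 1.27 and the ligase gene LIG3 by 0.82 and 1.06 on the log2 scale. In non-homologous end joining, 3 of 14 fell and 1 rose in HCC1937, and 6 fell and 1 rose in HCC1937+BRCA1 (3, 1, 6 and 1 adjusted over the list alone). XRCC4 fell by 0.95 and 0.89 and LIG4 by 0.67 and 0.73 on the log2 scale. The 1 higher in HCC1937 became 0 without any 1 of the 8 arrays. In camera, the adjusted p was 0.037 and 0.0177, and the adjusted p was 0.32 and 0.308 with an estimated correlation. After cyclic loess it was 0.102 and 0.0822.

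In nucleotide excision repair, 5 of 20 fell and 2 rose in HCC1937, and 8 fell and 2 rose in HCC1937+BRCA1 (5, 2, 8 and 2 adjusted over the list alone). The 5 became 3 without HCC1937 COH29 replicate 1 or control replicate 1, and the 8 became 5 without HCC1937+BRCA1 control replicate 1. GTF2H1, a TFIIH subunit gene, fell by 1.03 and 1.51 on the log2 scale. For the list, the camera adjusted p was 0.28 in HCC1937 and 0.0464 in HCC1937+BRCA1, the second with an adjusted p = 0.564 under an estimated correlation and 0.319 after cyclic loess. Of 21 DNA damage checkpoint genes, 7 fell and 3 rose in HCC1937, and 13 fell and 4 rose in HCC1937+BRCA1 (7, 3, 13 and 4 adjusted over the list alone). The 7 became 3 without HCC1937 COH29 replicate 1 and 2 without control replicate 2, the 3 became 1 without COH29 replicate 2, and the 13 became 8 without HCC1937+BRCA1 COH29 replicate 2 or control replicate 1. MDC1 fell by 0.93 and 0.99 and TOPBP1 by 0.78 and 0.87 on the log2 scale, and the ubiquitin ligase gene RNF168 rose by 0.67 in both lines. The list's camera adjusted p was 0.102 and 0.0177, the second with an adjusted p = 0.486 under an estimated correlation and 0.0948 after cyclic loess. Of 44 DNA replication genes, 6 fell and 6 rose in HCC1937, and 16 fell and 3 rose in HCC1937+BRCA1 (9, 6, 18 and 3 adjusted over the list alone). In HCC1937 the counts ran from 4 to 10 lower and from 3 to 6 higher over the alternatives, with 3 higher without either COH29 array or control replicate 2. POLE2 fell by 1.10 and 1.40 and GINS1 by 0.69 and 1.09 on the log2 scale, and CDC6 rose by 0.74 and 0.69. By camera the adjusted p was 0.328 and 0.00163, the second with an adjusted p = 0.486 under an estimated correlation and 0.153 after cyclic loess. Of 5 mismatch repair genes, 1 (0 to 2 over the alternatives, and 0 without any 1 HCC1937 array or either HCC1937+BRCA1 COH29 array) fell in HCC1937 and 2 in HCC1937+BRCA1 (0 and 2 adjusted over the list alone), with camera adjusted p = 0.73 and 0.227.

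**Figure D2:**
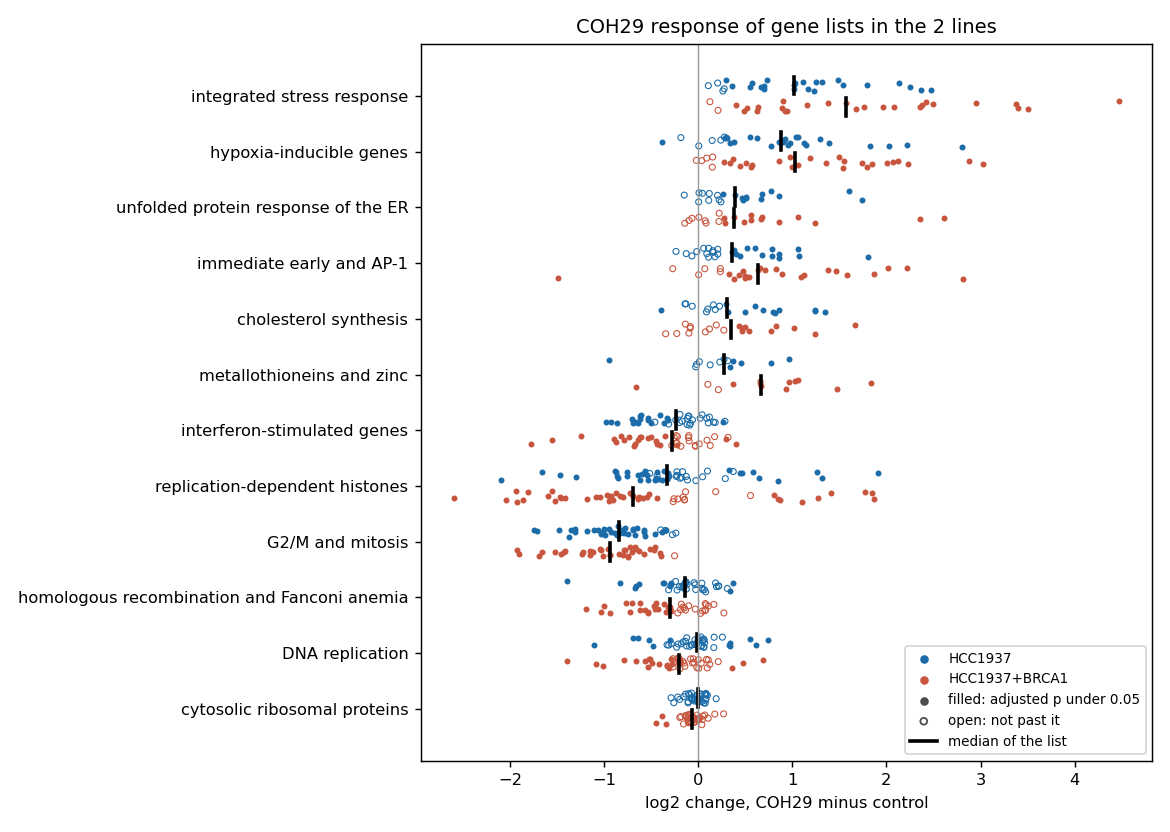
Log2 change with COH29 (COH29 minus control) of each measured member of 12 gene lists, in HCC1937 (blue) and HCC1937+BRCA1 (red); filled points passed the adjusted p threshold of 0.05, open points did not, and black bars are list medians. The integrated stress response medians are 1.02 and 1.57, the G2/M and mitosis medians -0.84 and -0.94.

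Among p53 target genes, a list that holds CDKN1A and GDF15, 13 of 27 rose and 4 fell in HCC1937, and 13 rose and 6 fell in HCC1937+BRCA1 (13, 4, 14 and 6 adjusted over the list alone). The 4 became 0 without HCC1937 COH29 replicate 1 or control replicate 1, 2 without COH29 replicate 2 and 1 without control replicate 2, and the 6 became 2 without HCC1937+BRCA1 control replicate 1. The kinase gene PLK3 rose by 1.29 and 1.92. In camera, the adjusted p was 0.000566 and 0.00271, and the adjusted p was 0.308 and 0.369 with an estimated correlation. Interferon-stimulated genes fell, 17 of 39 in HCC1937 with 1 higher, and 20 in HCC1937+BRCA1 with 2 higher (19, 2, 22 and 3 adjusted over the list alone). The 1 higher in HCC1937 became 0 without any 1 of the 8 arrays, and the 2 became 0 without HCC1937+BRCA1 COH29 replicate 2 or control replicate 1 and 1 without control replicate 2. IFI44L fell by 0.93 and 1.78 and PARP9 by 0.67 and 1.55 on the log2 scale. For the list, the camera adjusted p was 4.53e-06 and 1.17e-05, and the adjusted p was 0.308 and 0.32 with an estimated correlation. Of 25 genes of the NRF2 oxidative stress response, 8 rose and 6 fell in HCC1937 and 11 rose and 6 fell in HCC1937+BRCA1 (9, 6, 11 and 7 adjusted over the list alone), with camera adjusted p = 0.63 and 0.139. After cyclic loess the second was 0.0205, a call gained. The 6 became 3 in HCC1937 without control replicate 2, and in HCC1937+BRCA1 without COH29 replicate 1. The cystine transporter gene SLC7A11, also a member of the integrated stress response list, rose by 1.79 and 2.50. The heme oxygenase gene HMOX1 rose by 1.19 and 1.81. Of 27 apoptosis regulators, 8 rose and 3 fell in HCC1937, and 8 rose and 9 fell in HCC1937+BRCA1 (9, 5, 11 and 9 adjusted over the list alone), with camera adjusted p = 0.442 and 0.661. The 8 in HCC1937 became 5 without either COH29 array and 4 without either control array of that line, and the 3 became 1 without COH29 replicate 1 or control replicate 2. The pro-apoptotic gene BCL2L11 (BIM) rose by 1.21 and 1.80, and BIRC2 fell by 0.97 and 1.37 on the log2 scale.

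The remaining lists had no camera call for the drug, and leaving out 1 array moved some of their small counts by more than 1.5 times. Of 16 heat shock genes, 2 rose and 5 fell in HCC1937, and 5 rose and 4 fell in HCC1937+BRCA1 (2, 5, 5 and 4 adjusted over the list alone; adjusted p = 0.328 and 0.522). Of 13 iron genes, 2 rose and 1 fell, and 4 rose and 3 fell (3, 2, 5 and 3 adjusted over the list alone; adjusted p = 0.328 and 0.243). Of 10 aryl hydrocarbon receptor targets, 5 rose and 2 fell, and 4 rose and 3 fell (5, 4, 6 and 3 adjusted over the list alone; adjusted p = 0.63 and 0.272), with CYP1B1 at -1.99 and -1.70. Of 28 NF-kB and cytokine genes, 3 rose and 6 fell, and 7 rose and 7 fell (3, 6, 7 and 7 adjusted over the list alone). Their camera adjusted p was 0.532 and 0.779, with medians of 0.05 and 0.13 against means of -0.07 and -0.08, and the test pointed down in HCC1937 and up in HCC1937+BRCA1. Of 39 cytosolic ribosomal protein genes, 0 passed the threshold in HCC1937 and 3 fell in HCC1937+BRCA1 (0 and 0 adjusted over the list alone; adjusted p = 0.501 and 0.293). Among cell type markers, 1 of 13 basal genes rose and 3 fell, then 4 rose and 1 fell (1, 3, 4 and 1 adjusted over the list alone; adjusted p = 0.966 and 0.53). Of 23 luminal genes, 5 rose and 3 fell, then 7 rose and 3 fell (6, 3, 7 and 3 adjusted over the list alone; adjusted p = 0.902 and 0.125). Of 27 mesenchymal genes, 3 rose and 1 fell, then 4 rose and 0 fell (3, 1, 3 and 0 adjusted over the list alone; adjusted p = 0.272 and 0.125). Of 22 blood and endothelial genes, 1 rose and 4 fell, then 1 rose and 2 fell (1, 4, 0 and 2 adjusted over the list alone; adjusted p = 0.995 and 0.579), with the adhesion gene PECAM1 at -1.95 and -1.48. In HCC1937 their median was 0.14 and their mean -0.09, and the test pointed down. Dim genes read slightly higher with COH29. The median change of the 341 olfactory receptor genes was 0.13 in each line, and that of the mean of both lines was 0.13 before and 0.03 after cyclic loess.

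The drug comparisons of the lines share no arrays. Both lines called 3337 genes, of which 1329 rose in both, 1986 fell in both and 22 moved in opposite directions. Independent lists of these sizes would share 717 genes with the same direction, but lists called with a shared spread are not independent. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.815. A call in only 1 of the lines shows neither a difference nor its absence. By the interaction test, 63 of the 2858 genes called only in HCC1937+BRCA1 and 28 of the 842 called only in HCC1937 differed between the lines.

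**Figure D3:**
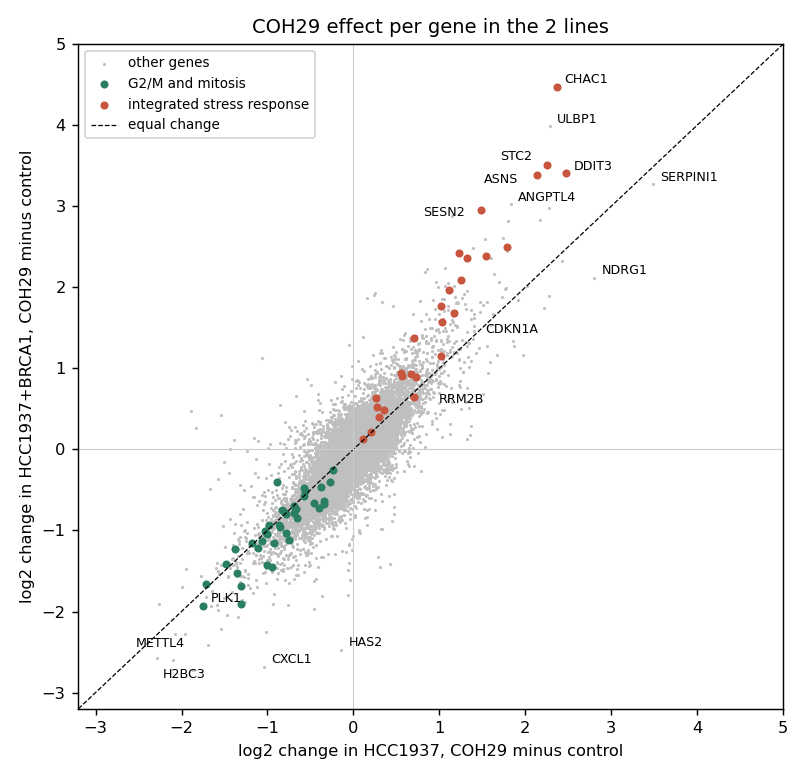
Log2 change with COH29 of each of 18417 genes in HCC1937 (horizontal axis) and HCC1937+BRCA1 (vertical axis), with integrated stress response genes in red, G2/M and mitosis genes in green and equal change as a dashed line. CHAC1 lies at 2.37 and 4.47, above the line, and PLK1 at -1.75 and -1.93, near it.

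The comparison of the drug effect between the lines, HCC1937 minus HCC1937+BRCA1, is the contrast named in the series design. CHAC1 had a smaller rise in HCC1937, with a difference of -2.11 ± 0.12 (SE, n = 2 arrays per group; adjusted p = 0.000438). The hypoxia-inducible gene ANKRD37 differed by -1.74 ± 0.26, having risen by 1.14 in HCC1937 and by 2.88 in HCC1937+BRCA1. HAS2 fell by 2.47 on the log2 scale in HCC1937+BRCA1 and had a change of -0.14 in HCC1937, a difference of 2.33 ± 0.19 (adjusted p = 0.00228). CXCL1 fell in both lines and less in HCC1937, with a difference of 1.64 ± 0.19. The testis-type linker histone gene H1-6 fell by 1.06 on the log2 scale in HCC1937 and rose by 1.13 in HCC1937+BRCA1. In all, 176 genes differed, 76 with a higher and 100 with a lower effect in HCC1937. Higher and lower refer to the signed log2 change, so for a gene that falls in both lines a higher effect is a smaller fall in HCC1937. The more frequent direction turned without dim genes (188 higher and 163 lower), with trend and robust moderation (327 and 239) and without HCC1937 COH29 replicate 1 (37 and 30). Limma without moderation of the variances called 3 genes. Leaving out replicates 1 and 2 in turn gave 42 and 41 for HCC1937 control, 67 and 62 for HCC1937 COH29, 50 and 65 for HCC1937+BRCA1 control, and 49 and 41 for HCC1937+BRCA1 COH29.

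Of the lists, integrated stress response genes had the smallest camera p. Of their 27 members, 12 had a lower effect in HCC1937 and 0 a higher one (17 and 0 adjusted over the list alone), with a median of -0.55. The 12 became 6 without HCC1937 COH29 replicate 2 or HCC1937+BRCA1 control replicate 1, and 5 without any other single array. They became 7 with the replicate block, 1 without moderation of the variances and 16 with trend and robust moderation, while the median lay between -0.61 and -0.51. The stress-induced gene SESN2 differed by -1.46, and STC2 and ASNS by -1.25 each. The list's camera adjusted p was 1.93e-22, and the adjusted p was 0.119 with an estimated correlation. Of 27 immediate early and AP-1 genes, 5 had a lower effect and 1 a higher one (12 and 3 adjusted over the list alone; camera adjusted p = 5.1e-08, and adjusted p = 0.411 with an estimated correlation). Over the alternatives 0 to 8 had a lower effect, with 0 without moderation. There were 1 without HCC1937+BRCA1 COH29 replicate 2, HCC1937+BRCA1 control replicate 1 or HCC1937 control replicate 1, 2 without HCC1937+BRCA1 COH29 replicate 1 or HCC1937 control replicate 2, and 3 without either HCC1937 COH29 array. FOS was at 0.16 in HCC1937 and rose by 1.87 in HCC1937+BRCA1, and DUSP1 differed by -1.36. Among 30 hypoxia-inducible genes, 6 had a lower effect and 1, NDRG1, a higher one (11 and 2 adjusted over the list alone; camera adjusted p = 3.08e-06, and adjusted p = 0.394 with an estimated correlation). Over the alternatives 0 to 8 hypoxia genes had a lower effect, with 0 without moderation and 3 without either HCC1937 COH29 array, either HCC1937+BRCA1 control array or HCC1937+BRCA1 COH29 replicate 2. Of 13 metallothionein and zinc genes, MT1X and MT1F had a lower effect and 0 a higher one (7 and 0 adjusted over the list alone; camera adjusted p = 1.56e-08, and adjusted p = 0.119 with an estimated correlation). Over the alternatives 0 to 5 had a lower effect, with 0 without either HCC1937 COH29 array, HCC1937+BRCA1 COH29 replicate 1, HCC1937+BRCA1 control replicate 1 or HCC1937 control replicate 2, and 1 without HCC1937+BRCA1 COH29 replicate 2 or HCC1937 control replicate 1. Of 50 histone genes, 4 had a higher effect in HCC1937 and 1 a lower one (20 and 3 adjusted over the list alone; camera adjusted p = 1.31e-06, and adjusted p = 0.308 with an estimated correlation), with H1-1 at 1.45. The list's medians with COH29 were -0.33 in HCC1937 and -0.69 in HCC1937+BRCA1, so its shift down was smaller in HCC1937. Over the alternatives 1 to 19 had a higher effect, with 19 with trend and robust moderation and 12 without dim genes. There were 1 without HCC1937+BRCA1 COH29 replicate 2, HCC1937+BRCA1 control replicate 1 or HCC1937 control replicate 2, and 2 without COH29 replicate 1 of either line or HCC1937+BRCA1 control replicate 2.

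No member of the homologous recombination, excision repair, mismatch repair, end joining, checkpoint or replication lists passed the interaction test over all genes. With trend and robust moderation 1 gene each of homologous recombination and nucleotide excision repair and 4 of replication passed with a higher effect in HCC1937, and of the checkpoint list 1 with a higher and 1 with a lower one. Without dim genes, 1 each of homologous recombination, nucleotide excision repair and replication passed. Adjusted over the list alone, 1 homologous recombination gene (UBE2T) and 2 nucleotide excision repair genes (ERCC4 at 0.70 and ERCC1 at 0.45, named after their values were seen) had a higher effect in HCC1937, and 0 in the others. The homologous recombination list had a median difference of 0.17 and the DNA replication list 0.18, with camera adjusted p = 0.000165 and 3.7e-05. Their medians with COH29 were -0.14 and -0.01 in HCC1937 and -0.30 and -0.20 in HCC1937+BRCA1, so the shift down was smaller in HCC1937. With an estimated correlation the adjusted p was 0.486 and 0.396. Genes grouped by level had median differences of -0.01 and -0.03 at mean levels of 5.14 and 7.08. At 8.72 and 10.68 the medians were 0.06 and 0.07, and 0.01 and -0.005 after cyclic loess. Part of the list medians may thus follow signal level. Camera after cyclic loess gave the lists adjusted p = 0.00385 and 0.00428. Over the alternatives the medians ran from 0.11 to 0.22 for homologous recombination and from 0.10 to 0.21 for replication. UBE2T, a Fanconi pathway gene, had the smallest p of the first list, with a difference of 0.53 ± 0.11 (adjusted p = 0.0751), and POLD3 of the second (0.53 ± 0.12, adjusted p = 0.0804). The G2/M and mitosis list had a median of 0.08 and 0 members past the threshold (camera adjusted p = 0.103).

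Without drug, HCC1937+BRCA1 differed from HCC1937 in 5749 genes. The antisense RNA ZNF667-AS1 was 7.07 ± 0.27 higher on the log2 scale (SE, n = 2 arrays per group), the neural adhesion gene CNTN1 6.22 ± 0.21, the glypican gene GPC6 5.42 ± 0.09 and the receptor gene ADGRL2 5.28 ± 0.10. Lower were the amino acid transporter gene SLC6A14 (-6.36 ± 0.16), the fatty acid receptor gene CD36 (-5.67 ± 0.13), the pluripotency marker gene ZFP42 (-4.76 ± 0.19) and the granzyme inhibitor gene SERPINB9 (-4.65 ± 0.12). RRM2 was 0.57 higher (adjusted p = 0.00153) and RRM2B was at -0.81 (adjusted p = 8.81e-05), while RRM1 and CDKN1A differed by -0.12 and 0.20 (adjusted p = 0.392 and 0.28). In all, 3016 genes were higher and 2733 lower in HCC1937+BRCA1, 487 and 437 of them at least 2-fold.

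Interferon-stimulated genes were lower in HCC1937+BRCA1, 25 of 39 with 2 higher (27 and 4 adjusted over the list alone), with a median of -0.68. The 2 became 1 without HCC1937+BRCA1 control replicate 1 or HCC1937 control replicate 2. MX2 was at -3.12 and OAS2 at -1.99. Camera gave adjusted p = 1.31e-10, and adjusted p = 0.245 with an estimated correlation. Of the integrated stress response list, 14 of 27 members were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 3.25e-05, and adjusted p = 0.308 with an estimated correlation). The cystathionine lyase gene CTH was at -3.12 and STC2 at -1.50. The aldo-keto reductase genes AKR1C1 (-3.23) and AKR1C2 (-3.56) are in the NRF2 list, where 14 of 25 were lower and 5 higher (15 and 5 adjusted over the list alone; camera adjusted p = 0.0103, and adjusted p = 0.455 with an estimated correlation). The 14 became 9 without HCC1937 control replicate 2, and the 5 became 3 without HCC1937 control replicate 1 or HCC1937+BRCA1 control replicate 2. These paralogs, AKR1C1 and AKR1C2, are close in sequence, and their probe sets may share signal. Immediate early genes were lower in 17 of 27 and higher in 2 (17 and 5 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.564 with an estimated correlation). Without HCC1937+BRCA1 control replicate 1 or HCC1937 control replicate 1 the 17 became 11, and the 2 became 1 without either HCC1937+BRCA1 control array or HCC1937 control replicate 2. NF-kB and cytokine genes were lower in 14 of 28 and higher in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.000916, and adjusted p = 0.486 with an estimated correlation), with PTGS2 (COX-2) at -3.53. The 4 became 2 without either HCC1937 control array or HCC1937+BRCA1 control replicate 2, and 1 without moderation of the variances. Cholesterol synthesis genes were higher in 10 of 20 and lower in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00239, and adjusted p = 0.518 with an estimated correlation). Of 50 histone genes, 16 were higher and 1 lower (16 and 2 adjusted over the list alone; camera adjusted p = 0.00271, and adjusted p = 0.486 with an estimated correlation), and the 1 became 0 without any 1 of the 4 control arrays and 2 without either HCC1937+BRCA1 COH29 array. Of 13 metallothionein and zinc genes, 8 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.00149, and adjusted p = 0.245 with an estimated correlation). Of 13 iron genes, 1 was higher and 7 lower (1 and 7 adjusted over the list alone; camera adjusted p = 0.0296, and adjusted p = 0.32 with an estimated correlation).

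Cell type markers also differed between the lines. The mesenchymal markers CDH2 (N-cadherin) and VIM (vimentin) were 3.89 and 3.56 higher in HCC1937+BRCA1. Of the 27 mesenchymal genes, 7 were higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.0903). Luminal markers were lower in 8 of 23 and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0306, and adjusted p = 0.55 with an estimated correlation), with the transcription factor genes ELF5 at -3.66 and SPDEF at -2.15. The 1 became 0 without any 1 HCC1937+BRCA1 array or HCC1937 control replicate 2. Basal markers were higher in 5 of 13 and lower in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0371, adjusted p = 0.518 with an estimated correlation, and 0.0519 after cyclic loess). The desmosomal gene DSC3 was 4.47 higher and the keratin gene KRT5 was at -1.70. Of 22 blood and endothelial markers, 0 were higher and 4 lower (0 and 4 adjusted over the list alone; camera adjusted p = 0.074), with CD14 at -3.77. Homologous recombination genes were higher in 8 of 39 and lower in 5 (8 and 5 adjusted over the list alone; camera adjusted p = 0.522). The 8 became 5 without HCC1937+BRCA1 control replicate 2, and the 5 became 3 without that array or HCC1937 control replicate 2. Those of G2/M and mitosis were higher in 5 of 38 and lower in 8 (5 and 8 adjusted over the list alone; camera adjusted p = 0.857). The 5 became 3 without HCC1937+BRCA1 control replicate 2 and 2 without any other control array, and the 8 became 5 without HCC1937+BRCA1 control replicate 2.

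Averaged over both lines, 4 treated against 4 control arrays, COH29 raised CHAC1 by 3.42 ± 0.06 (SE), SERPINI1 by 3.37 and ULBP1 by 3.13, and lowered METTL4 (-2.43), H2BC3 (-2.34) and YAE1 (-2.29). This comparison called 7746 genes, 3556 higher and 4190 lower. With each array shifted to the same median, 58.8% of the calls were higher in place of 45.9%. All 38 measured G2/M and mitosis genes fell, and 26 of 27 integrated stress response genes rose (38 and 26 adjusted over the list alone). By camera the adjusted p was 3.26e-22 and 9.77e-19, and the adjusted p was 0.245 and 0.119 with an estimated correlation.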

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

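The tests of array scale, starting level and single arrays for the stress genes, and those of swapped arrays and saturation for BRCA1, were chosen after the results were seen.

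Results appear here because the drug effect differed between the lines in the interaction test, with 176 genes in all. Differences are HCC1937 minus HCC1937+BRCA1. The largest positive ones were HAS2 (2.33), LINC00417 (1.84), ZNF826P (1.75), CD180 (1.73) and CXCL1 (1.64), and the largest negative ones SPIC (-2.37), H1-6 (-2.20), CHAC1 (-2.11), B3GALT5-AS1 (-1.96) and ANKRD37 (-1.74). Lists called by camera had median differences of 0.17 (homologous recombination and Fanconi anemia), 0.18 (DNA replication), 0.30 (histones), -0.55 (integrated stress response), -0.039 (unfolded protein response), -0.13 (heat shock), -0.12 (NRF2), -0.42 (metallothioneins and zinc), -0.18 (hypoxia), -0.30 (immediate early and AP-1) and -0.090 (luminal markers). With an estimated correlation none of these lists was called, and the smallest adjusted p was 0.119. Brighter genes in general had median differences of 0.06 and 0.07 at mean levels of 8.72 and 10.68. The positive medians of the homologous recombination and replication lists may thus in part follow signal level.

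The larger rise of integrated stress response genes in HCC1937+BRCA1, seen in CHAC1, STC2, ASNS and SESN2, was weighed against 3 technical explanations, and an effect of BRCA1 itself was not tested apart from other differences of the lines. A difference in array scale would stretch all changes alike. The slope of the HCC1937+BRCA1 effect on the HCC1937 effect was 0.502 steeper over this list than over the G2/M and mitosis list (95% bootstrap interval over genes 0.365 to 0.643), so both lists were not stretched alike. The lists' differences between the lines had been seen before, so the slopes restate them and are no separate test. They also cannot exclude a stretch that depends on signal level or on the direction of change. After cyclic loess and in the other alternatives, the list's median difference lay between -0.61 and -0.51. A single array does not account for the larger rise, since the list's median difference stayed at least 0.518 in size whichever array was left out. For the list, a lower starting level with the same end level cannot be told apart from a stronger response, since its median was -0.31 in untreated HCC1937+BRCA1 relative to HCC1937 and 0.18 between the treated groups, with an interval of -0.05 to 0.40 that holds 0. Single genes differed, as the treated means in HCC1937+BRCA1 and HCC1937 were 12.35 and 11.07 for CHAC1, 11.36 and 10.48 for ASNS, 11.62 and 10.77 for DDIT3 (8.22 and 8.29 untreated) and 10.78 and 11.04 for STC2.

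BRCA1 read no higher on the arrays labelled HCC1937BRCA1, and single mislabelled arrays or a saturated probe set could hide a rise. All 8 arrays correlated best with the other array of their own group, which argues against a swap of single arrays between the lines. The BRCA1 level was at most at percentile 88.6 of the genes on an array, so other genes read higher on every array. BRCA1 lies between PSME3 and GRN, a run of neighbours looked up after the BRCA1 level was seen. Of its 25 genes, 24 were lower in untreated HCC1937+BRCA1, with a median of -0.46. A lower dose of the line's own gene, which was not measured, could thus also hide a rise. This, a complete exchange of the line names, loss of the exogenous gene, or a transgene transcript that the probe set reads poorly stays open. No value here decides between them.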

How the results depend on the processing

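The crossed block and cyclic loess for gene lists were chosen after the data were seen, and the other alternatives before.

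Among 582 results for named genes, 9257 of 9682 alternatives kept the side of the threshold, 377 lost the call and 48 gained one. With 0 exceptions, a change called in the main fit or in the alternative kept its direction, which was not compared where neither made a call. In all, 471 of 546 calls held in each alternative, counting all but the minimum log2 change. Most named genes were chosen for large changes or small p in these data, which favours stable calls. That minimum, an absolute log2 change of 1, kept 284 of the 546 calls and ended 262. Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested unless named. The same minimum, a stricter rule by construction, left 351 genes in HCC1937, 675 in HCC1937+BRCA1, 74 for the difference of effects, 924 between the untreated lines and 446 averaged over both lines. The difference of effects, with 176 genes, gave 351 without dim genes and 566 with trend and robust moderation, both with more genes higher than lower, then 3 without moderation and 106 with the replicate block, 103 of them among the 176. Leaving out 1 array, where the lone array of a group is assumed to vary like the other groups, gave 41 to 67 genes for the difference of effects. The lowest, 41, came without HCC1937 control replicate 2 or HCC1937+BRCA1 COH29 replicate 2. The other values were 42 without HCC1937 control replicate 1, 67 and 62 without HCC1937 COH29 replicate 1 and 2, 50 and 65 without HCC1937+BRCA1 control replicate 1 and 2, and 49 without HCC1937+BRCA1 COH29 replicate 1. For COH29 in HCC1937 leaving out 1 array gave 2336 to 4012 genes, with 2336 without control replicate 2, 2392 without control replicate 1 and 2642 without COH29 replicate 1. It gave 4171 to 6400 in HCC1937+BRCA1, 3988 to 5751 between the untreated lines and 6121 to 8061 averaged over both lines. An estimated correlation in camera, which also tests on few degrees of freedom, called 0 lists in each of the 5 comparisons. Fry, which asks another question, called 17 lists in HCC1937, 24 in HCC1937+BRCA1, 7 for the difference, 18 between untreated lines and 23 averaged, against 11, 15, 11, 11 and 14 by camera. Camera after cyclic loess called 9, 12, 11, 10 and 11.

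Whether the replicate numbers pair the arrays cannot be told from these values. Deviations of arrays with the same number correlated at 0.0367 and 0.26 within a line and at -0.204 to -0.0857 across the lines. The negative values give no sign of pairing by number across the lines, but numbers crossed between the lines could also give such signs. With the replicate block, 3779, 5772, 5389 and 7243 genes were called in HCC1937, in HCC1937+BRCA1, between the untreated lines and averaged. With numbers crossed between the lines, the counts were 4777, 7021, 6182 and 8668, and 199 for the difference of effects. The number of arrays limits the precision of each result, and no background signal was used.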

Other observations

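The gene families below, the genes named from them, the runs of neighbours named and the restriction of the splits were chosen after their values were seen, while the neighbour test was stated before its result.

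Genes of autophagy, the recycling of cell contents in lysosomes, were more often higher than lower with COH29. Of 29 measured, 13 rose and 2 fell in HCC1937, and 12 rose and 5 fell in HCC1937+BRCA1. MAP1LC3B (LC3B), which coats the autophagosome, rose by 1.53 and 2.59, WIPI1 by 1.37 and 1.09, the kinase gene ULK1 by 0.59 and 1.20, and the cargo receptor gene SQSTM1 (p62) by 0.67 and 0.86. The family's medians were 0.26 and 0.24. Mitochondrial ribosomal protein genes were lower in 19 of 70 in HCC1937 with 1 higher, and in 37 in HCC1937+BRCA1 with 0 higher. Their medians were -0.23 and -0.35. MRPL44 fell by 0.79 and 1.30 and MRPL46 by 0.51 and 1.39 on the log2 scale. Of 21 nucleoporin genes, which build the nuclear pore, 10 fell in HCC1937 and 17 in HCC1937+BRCA1, with 0 higher. NUP205 fell by 0.61 and 0.83 on the log2 scale and NUP35 by 0.58 and 0.84. After cyclic loess the medians of the autophagy, mitochondrial ribosomal and nucleoporin genes were 0.18, -0.20 and -0.32 in HCC1937 and 0.24, -0.24 and -0.42 in HCC1937+BRCA1, and no scaling tried turned their direction.

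Without drug, 141 of 439 zinc finger genes named ZNF were higher in HCC1937+BRCA1 and 31 lower, the others did not pass the test, and the median of all was 0.14. ZNF415 was 3.91 higher, ZNF649 3.29, ZNF577 2.68 and ZNF610 2.67.

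The differences between the untreated lines may in part follow gains or losses of chromosome parts, a hypothesis stated before its test. Neighbouring genes would then differ in the same direction. Over 9206 genes in the upper part of the range of mean level, ordered along the genome, adjacent genes' line differences correlated at 0.422 (Spearman), against 0.0262 for the drug effect on the same genes and at most 0.0362 in 1000 shuffled orders. Of 359 runs of 25 adjacent genes, 130 had a median line difference of at least 0.2 in size, against 23 for the drug effect and at most 20 in the shuffled orders. All 25 genes of the run from POMP to VWA8 were lower in HCC1937+BRCA1, with a median of -1.02, as were all 25 from CCNJ to BLOC1S2 (-0.67). In the run from WASHC1 to BNC2, 24 of 25 were higher, with a median of 0.79, and in that from USP40 to D2HGDH 23 of 25 (0.91). Neither copy number nor genotype was measured here, and shared regulation of neighbours, such as of the ZNF clusters, can add to the correlation. Which differences of the lines follow from BRCA1 cannot be read from these arrays.

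The count of 7746 genes for COH29 averaged over both lines was compared with other splits of the 8 arrays into 4 and 4. Over all 34 splits that could be fitted, 1, the real one, called as many, but the lines themselves differ, so the arrays can be exchanged only within a line. The 18 splits with 2 arrays of each line on either side are too few for a share under 0.05. The highest other count was 176, from the split that matches the difference of drug effects.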
